A study of Homo sapiens with 2 samples.

How the data were processed

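Recombinant DNA-binding domain of the human glucocorticoid receptor was mixed with fluorescently labelled double-stranded DNA and run on a native gel. Bound and unbound bands of the lane with 2 µM protein were cut out, amplified with at most 10 rounds of PCR and sequenced, per the labels' protocols. The first experiment held libraries 1 to 4 with 10% positive and 5% negative control. The second held library 5 with 5% positive control, per the labels. The protocol text also speaks of similar control ratios in both, and a negative control was not analysed here for library 5. Both samples are single experiments, so nothing was averaged over replicates.

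The deposited counts are whole numbers of bound and unbound reads per site. The deposited ratio is bound over unbound reads, and it equalled the counts' own ratio within 0.0006 in all 1815 and 2748 sites. The deposited energies are on a natural log scale in kT relative to the positive control, per the file headers, and differed by at most 0.000918 and 0.000714 kT from the same formula applied to the counts. The read trimming, matching and filtering steps are not given in the sources used here. The lowest total per site was 51 reads with libraries 1 to 4 and 22 with library 5. The base after each site marks its library, per the file headers, which also say that the positive control was over-enriched; the site table lists the reference once per experiment.

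The library patterns were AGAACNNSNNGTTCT, AGAANNGGGNNNTCT, AGAACAGGGTGNNNN, AGAACAGGGCNNNTCT and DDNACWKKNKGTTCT for libraries 1 to 5, where S is C or G, D is A, G or T, W is A or T and K is G or T. They held 512, 1024, 256, 64 and 2304 designed sites.

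Energies were recomputed from the counts after adding 0.5 to each, for sites with at least 50 bound plus unbound reads, which left out 182 sites of the second experiment, all outside the library 5 pattern. SE is the square root of the summed reciprocal counts. The tests, the alternatives and the rule for named sites were fixed before the data were examined, except where the text says otherwise. One-base variants were tested with two-sided Fisher exact tests. Base, pair, spacing and mirror effects were tested over matched contexts with two-sided sign-flip permutation tests, with 100000 resamples or exact under 10 contexts, and Benjamini-Hochberg adjustment. The 42 half-site and 12 spacer effects were adjusted separately, and adjusting all 54 together left the same 40 and 9 calls. Correlations were tested by permuting pairings. Additive models were fitted by least squares per library with 10-fold cross-validation. Where a value has no test, its spread is a bootstrap SD over sites, since there are no replicates.

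The named sites are the reference, the negative control, the one-base variants, the 5 tightest and 5 weakest sites of each library, the 5 largest pair dependences and the 3 sites that differed most between experiments. Alternatives covered the read minimum, the added count, misreads of the reference, the ratio of the weakest sites as background, the deposited energies, thinning to equal depth, and other weights, contexts and reference values.

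The calculations were tested on simulated counts with the sites and depths of libraries 1 and 5. All 6 pairs changed by 1 kT were recovered in each, with 0 of the other pairs called among 66 and 83 tested. The simulated counts held counting error only, and their energies had no weakest level. They therefore give no error rate for pair calls near such a level. Library 3, which holds 17 of the 24 pairs called in the data, was not simulated. In 20 simulations each, all 129 and 146 base effects of 0.5 kT were called, and 3 of 131 and 5 of 134 unchanged ones were. Of 175 simulated unchanged sites, 4.57% had a Fisher p under 0.05. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.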

Results

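The data measured how tightly the DNA-binding domain of the human glucocorticoid receptor bound a large set of short DNA sites. The receptor is a steroid hormone receptor and transcription factor that binds DNA as a dimer, each subunit contacting one half-site of 6 bases on either side of a spacer of 3 bases. Recombinant protein at 2 µM was mixed with pools of double-stranded sites, bound and free DNA were separated on a native gel, and both fractions were sequenced. There were 2 binding experiments, 1 with libraries 1 to 4 and 1 with library 5, each run once, so no value has a replicate error. The energy of a site is the natural log of its unbound to bound ratio minus that of the reference site AGAACAGGGTGTTCT, in kT, and a higher energy is weaker binding. Positions are counted from 1 at the 5' end of the reference, with half-sites at 1 to 6 and 10 to 15 and the spacer at 7 to 9. Libraries 1 to 4 gave 1815 sites from 2310688 bound and 2916653 unbound reads. Library 5 gave 2748 sites from 1268465 bound and 1743678 unbound reads. The median site had 1197 reads in the first experiment and 923.5 in the second. Errors given as SE come from read counts and cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

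The control sequences set the scale of the assay. The reference, which served as positive control, had a bound to unbound ratio of 7.50 with libraries 1 to 4 and 8.10 with library 5. It took 79.6% of the bound reads and 8.41% of the unbound reads in the first experiment, and 19.3% and 1.73% in the second. The negative control TACTAATGTACTAGC, read in the first experiment, had a ratio of 0.112, an energy of 4.20 kT ± 0.0097 (SE), or 66.8-fold weaker than the reference. The file headers warn that the ratio of the over-enriched positive control may be inaccurate, and every energy is relative to it.

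The libraries differed in how much binding they kept. Library 1, which varied positions 6 to 10, averaged 2.55 kT ± 1.31 (SD over 490 sites), and 76 of its sites lay under 1 kT. Library 2, which varied positions 5, 6 and 10 to 12, averaged 4.15 kT ± 0.264 (SD over 1024 sites), and 97.3% of its sites were weaker than a line 0.399 kT below the negative control. Library 3, which varied positions 12 to 15, averaged 3.75 kT ± 0.735 (SD over 256 sites), and 74.6% of its sites were past the same line. Library 5, which varied positions 1 to 3 and 6 to 10, averaged 2.81 kT ± 0.814 (SD over 2304 sites). Of the 512 designed sites of library 1, 22 were not listed, and 21 of these had C at position 6, one of the weakest bases there, so the averages of library 1 leave out part of its weak end.

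Mean energy rose with the number of changed bases in the half-sites in both experiments. In libraries 1 to 3, sites with 0 half-site differences averaged 0.11 kT ± 0.449 (SD, n = 32), those with 1 difference 1.97 kT ± 1.06 (SD, n = 208), those with 2 differences 3.44 kT ± 0.837 (SD, n = 403) and those with 3 differences 4.09 kT ± 0.221 (SD, n = 378). With 4 or more differences the mean was 4.19 kT ± 0.121 (SD, n = 729), at the level of the negative control. Library 1 varied only positions 6 and 10 of the half-sites, so all sites with 3 or more differences came from libraries 2 and 3. Number and position of the changes therefore cannot be told apart in libraries 1 to 3. In library 5 the same classes averaged 1.02, 1.59, 2.16, 2.77 and 3.48 kT over 16, 144, 496, 816 and 832 sites. In library 1, sites with the left half-site AGAACA kept and the right one changed averaged 1.89 kT ± 1.01 (SD, n = 96), and sites with the right half-site TGTTCT kept and the left one changed averaged 1.91 kT ± 1.04 (SD, n = 94). Apart from unlisted sites, these are the same duplexes read in opposite directions, so the means do not compare the half-sites. In libraries 1 to 3, palindromic half-sites other than those of the reference averaged 3.08 kT ± 1.01 (SD, n = 96). These are counts of sites in 1 experiment each, and no test was run on them.

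**Figure D1:**
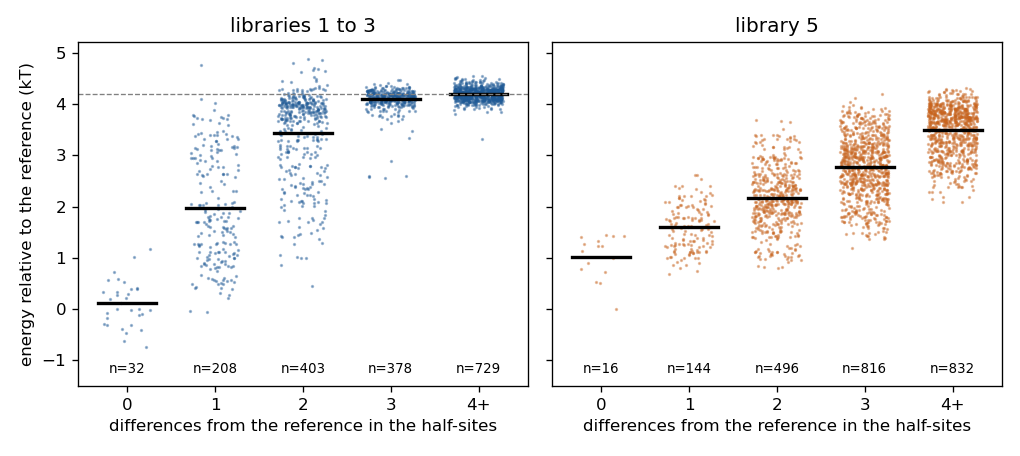
Energy relative to the reference (kT) of each designed site, by the number of half-site bases that differ from the reference, for libraries 1 to 3 and for library 5, with points for sites, black bars for means and a dashed line for the negative control at 4.20 kT. The means rise from 0.11 to 4.19 kT in libraries 1 to 3 and from 1.02 to 3.48 kT in library 5.

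Single base changes differed in how much binding they cost. In libraries 1 to 3, the highest means over 3 substitutions were at positions 5, 11, 14 and 12, with 3.73, 3.57, 3.28 and 3.25 kT. At position 14 the energies ran from 2.58 to 3.88 kT, and C14G, at 48.5-fold, was the weakest one-base variant. The bound to unbound ratio was 0.154 for C14G and 0.182 for C5G, close to the 0.112 of the negative control. Energies this close to that level may understate what these changes cost. At positions 6 and 10, C and G respectively cost most: A6C lay at 3.36 kT ± 0.05 (SE) and T10G at 3.13 kT ± 0.034 (SE), against 1.61 kT for A6G and 1.52 kT for T10C. At position 13 the energies ran from 0.55 kT for T13A to 1.45 kT for T13G, and at position 15 from 0.60 kT for T15C to 1.82 kT for T15A, and the spacer changes at position 7 lay between 0.0092 and 0.21 kT. In library 5, changes at position 2 cost 1.62 to 1.73 kT, those at position 3 cost 1.05 to 1.13 kT, and A1G and A1T cost 0.80 and 1.57 kT.

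Of the 45 one-base variants that the designs contain, 40 bound weaker than the reference, 26 of 31 in libraries 1 to 3 and 14 of 14 in library 5, with none tighter. A call needed an adjusted p under 0.05 in a two-sided Fisher exact test on the reads (Benjamini-Hochberg over 58 variants) and an energy over 0.399 kT, which is 2 times the error from reverse-complement pairs. The largest adjusted p among the calls was 2.63e-15 in libraries 1 to 3 and 1.07e-11 in library 5. The 5 variants not called were G7A, G7C, G7T, G8C and G9A, at 0.0092 to 0.40 kT. The calls of library 5 depend on the reference itself: all 14 variants lay tighter than the other library 5 sites predict, by 0.51 kT ± 0.265 (SD), and with the reference set to the energy those sites predict for it, 1 was called weaker and 5 tighter. That prediction is uncertain, since the same kind of prediction missed the reference by 0.89 kT in library 2. In libraries 1 to 3 the same replacement, chosen after the data were seen, gave 25 weaker and 0 tighter. With the ratio of the weakest sites subtracted as background, 22 and 8 were called weaker. The energy needed for a call also rose there, to 2 times an error from reverse-complement pairs of 0.487 kT. The lower counts therefore do not show smaller energies.

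**Figure D2:**
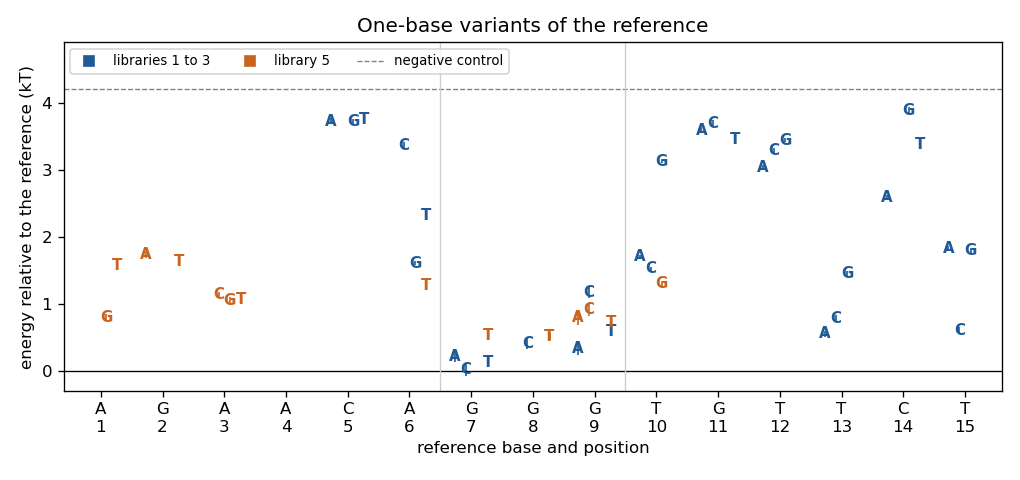
Energy relative to the reference (kT) of each designed one-base variant, by position, drawn as the letter of the new base, where blue is libraries 1 to 3, orange is library 5, bars are counting SE where they exceed the letter, vertical lines bound the spacer and the dashed line is the negative control. Positions 5, 11 and 12 hold variants only above 3 kT, and the spacer holds none above 1.17 kT.

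Averaged over all matched contexts, most half-site changes weakened binding. In library 1, A6C weakened binding by 2.54 kT ± 0.84 (SD, n = 107 contexts), A6T by 1.36 kT ± 0.421 (SD, n = 127) and A6G by 0.94 kT ± 0.363 (SD, n = 128). The mirrored changes T10G, T10A and T10C weakened it by 2.42, 1.35 and 0.91 kT. Over all contexts of library 1 these are the same duplexes read in the opposite direction, so they are not a separate measurement. In library 5, T10G weakened binding by 1.09 kT ± 0.304 (SD) in 1152 of 1152 contexts, G2T by 0.84 kT, G2A by 0.76 kT and A6T by 0.63 kT. A1G went the other way in library 5, binding tighter by 0.13 kT on average (mean difference -0.13 kT ± 0.181, SD) in 609 of 768 contexts, although as a single change it was weaker than the reference. In library 2 the effects were 0.052 to 0.17 kT, in contexts that averaged over 4 kT with the reference base. In library 3, changes at position 12 weakened binding by 0.95 to 1.01 kT and at position 14 by 0.71 to 0.92 kT. Of 42 half-site effects, 40 passed the sign-flip permutation test over contexts after Benjamini-Hochberg adjustment, 39 weaker and 1 tighter, with a largest adjusted p of 0.00127. T13A and T15C in library 3 did not pass the permutation test over 64 contexts, at 0.033 kT (adjusted p = 0.248) and 0.017 kT (adjusted p = 0.471). Contexts are sites of one experiment and not replicates of it.

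Spacer bases changed binding in both directions. In library 1, with both half-sites intact, the 32 spacers ran from -0.75 kT ± 0.091 (SE) for AGAACATCATGTTCT, 2.11-fold tighter than the reference, to 1.17 kT ± 0.094 (SE) for AGAACAGGCTGTTCT, 3.23-fold weaker. The other tightest sites of library 1 were AGAACACGATGTTCT at -0.63 kT, AGAACATCGTGTTCT at -0.46 kT, AGAACATCTTGTTCT at -0.40 kT and AGAACACCGTGTTCT at -0.38 kT. In the opposite orientation, the duplexes of the spacers TCA, TCT and CCG lay at -0.29, -0.30 and 0.0092 kT, and those of CGA and TCG are each other's reverse complement. Over all contexts of library 1, G7T and G7C gave tighter binding (mean differences -0.59 kT ± 0.455 and -0.51 kT ± 0.422, SD, n = 113 and 112), and G9C and G9T gave weaker binding by 0.63 kT ± 0.361 and 0.41 kT ± 0.421 (SD, n = 118 and 122). G7A, G8C and G9A in library 1 did not pass the permutation test, with adjusted p of 0.0603, 0.278 and 0.695. For G8C this was set by the design, since the sites with C there are the reverse complements of those with G. In library 5, G7T gave -0.28 kT ± 0.252 (SD) in 1152 contexts and G9C gave 0.16 kT ± 0.169 (SD) in 576. G8T, G9A and G9T were smaller there, at -0.070, -0.033 and 0.061 kT. As single changes from the library 5 reference, G7T, G8T and G9A were weaker instead, at 0.52, 0.51 and 0.79 kT. Of 12 spacer effects, 9 passed, 4 weaker and 5 tighter, with a largest adjusted p of 5.33e-05 in the same permutation test. In library 1, G7C and G9C are one contrast read in opposite directions with its sign turned, so these calls are not all separate.

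Spacers with fewer G or C bases bound tighter in library 1. Between intact half-sites the mean was -0.23 kT ± 0.282 (SD, n = 8) with 1 G or C, 0.14 kT ± 0.381 (SD, n = 16) with 2, and 0.40 kT ± 0.524 (SD, n = 8) with 3. Across the 32 spacers, Pearson's r of energy and G or C count was 0.50 (permutation p = 0.00375), Spearman's rho was 0.498 (permutation p = 0.0042), and r was 0.417 without the 2 spacers farthest from the median. The 32 spacers are 16 duplexes, each read in both directions with the same G or C count. The permutations treated them as independent, so these p-values are too small. In library 5, r over the 16 intact sites was -0.751 (permutation p = 0.00064), and -0.45 (permutation p = 0.184) without the reference and its one-base variants. This correlation was chosen after the data were seen. Sites with C at position 8 averaged 0.057 kT and those with G 0.16 kT, a paired difference of -0.11 kT ± 0.361 (SD, n = 16 pairs, permutation p = 0.245). Both groups are the same 16 duplexes read in opposite directions, so this difference was small by design and does not test the central base.

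**Figure D3:**
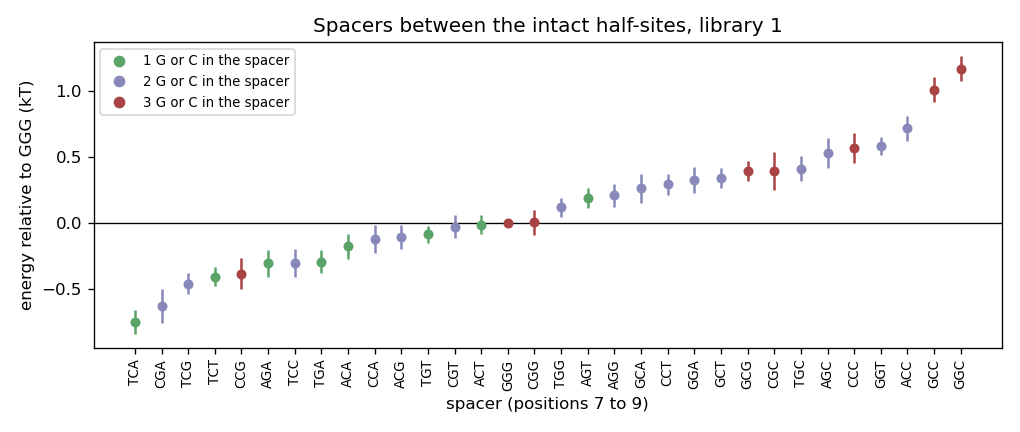
Energy relative to the reference spacer GGG (kT) of the 32 spacers of library 1 between intact half-sites, in order of energy, with points for single sites, bars for counting SE and colour for the number of G or C bases. Energies run from -0.75 kT for TCA to 1.17 kT for GGC.

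Sites with a spacer of 4 bases bound at the level of the negative control. The 64 sites of library 4, in which a C lengthens the spacer, averaged 4.20 kT ± 0.111 (SD), and 62 of them lay within 0.399 kT of the negative control. With the same 3 varied bases, the matched sites with a spacer of 3 bases averaged 3.82 kT ± 0.69 (SD). The longer spacer was weaker by 0.37 kT ± 0.699 (SD) on average and in 55 of 64 pairs (two-sided sign-flip permutation p = 1e-05, the smallest that 100000 resamples can give). The largest gap was between AGAACAGGGCTGTTCT at 4.16 kT and the reference. In the 59 pairs whose shorter site was itself within 1 kT of the negative control, the difference was 0.21 kT ± 0.251 (SD, permutation p = 1e-05), so the mean gap is limited by how weak those sites already were. In the other 5 pairs it was 2.33 kT. With the ratio of the negative control subtracted it was 2.31 kT ± 2.01 (SD) over the 20 pairs with both sites above that ratio, where the energies of the longer sites rest on small remainders. The tightest sites of library 4 were AGAACAGGGCGTCTCT, AGAACAGGGCGTATCT, AGAACAGGGCGTTTCT, AGAACAGGGCGTGTCT and AGAACAGGGCTATTCT, at 3.65, 3.77, 3.85, 4.04 and 4.12 kT. Its weakest were AGAACAGGGCCCATCT, AGAACAGGGCAACTCT, AGAACAGGGCACGTCT, AGAACAGGGCAGATCT and AGAACAGGGCTCATCT, at 4.29 to 4.33 kT. In the first 4 of the tightest sites, the varied bases begin with G and T. Read with a spacer of 3 bases, these fall on positions 11 and 12, where the reference has the same bases. Which spacing these sites were bound with was not tested.

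The weakest sites of library 1 were AGAACCAGCAGTTCT at 4.88 kT ± 0.403 (SE), AGAACCCGGGGTTCT, AGAACCACCAGTTCT, AGAACCAGCTGTTCT and AGAACCTCAGGTTCT, each with 4 to 7 bound reads. In the opposite orientation the same 5 duplexes lay tighter, at 4.28, 4.28, 4.04, 3.63 and 3.85 kT. In library 2 the tightest sites after the reference were AGAACAGGGCGTTCT, AGAACGGGGTGTTCT, AGAACAGGGAGTTCT and AGAACGGGGCGTTCT, at 1.52, 1.61, 1.70 and 2.10 kT. Its weakest were AGAAACGGGAACTCT, AGAAACGGGCGATCT, AGAAGGGGGCGCTCT, AGAACCGGGCTCTCT and AGAAGCGGGTTCTCT, at 4.50 to 4.55 kT. In library 3 the tightest after the reference were AGAACAGGGTGTACC, AGAACAGGGTGTACT, AGAACAGGGTGTTCC and AGAACAGGGTGTCCT, at 0.45, 0.55, 0.60 and 0.78 kT. Its weakest were AGAACAGGGTGCGAA, AGAACAGGGTGCGTG, AGAACAGGGTGGGAA, AGAACAGGGTGCCTG and AGAACAGGGTGGAGC, at 4.36 to 4.43 kT. In library 5 the tightest after the reference were AGAACAGTGTGTTCT, AGAACATGGTGTTCT, GGAACATGCTGTTCT and AGAACAGGTTGTTCT, at 0.51, 0.52, 0.69 and 0.72 kT. Its weakest were TTGACTTGCGGTTCT, TTCACTGTCGGTTCT, TTAACTGGCGGTTCT, TTTACTGGCGGTTCT and GTGACTTGCGGTTCT, at 4.28 to 4.30 kT.

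By R2, adding up independent base effects described libraries 1 and 5 better than libraries 2 and 3, and library 2 has the smallest spread of the 4 to describe. The R2 of the additive model on left-out sites, with 10 folds, was 0.888 in library 1, 0.927 in library 5, 0.575 in library 3 and 0.223 in library 2. The RMS residual was 0.42, 0.219, 0.454 and 0.229 kT in the same order, each above the RMS counting SE of 0.169, 0.0785, 0.0954 and 0.0901 kT and above the 0.199 kT of reverse-complement pairs. An additive model with a fitted weakest energy, chosen after the data were seen, raised this R2 to 0.942, 0.937, 0.92 and 0.805 in the same order. Without the reference and its one-base variants, the model with a weakest energy gave 0.942, 0.939, 0.861 and 0.475.

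Some pairs of changes bound tighter together than the sum of their single effects. Of 293 pairs of substitutions tested, 24 passed both conditions, an adjusted p under 0.05 in the sign-flip permutation test and a mean over 0.5 kT in size, 20 below 0 and 4 above. The 5 largest were T12G, T12C and T12A with C14G in library 3, at -2.28, -2.21 and -2.12 kT (SD 0.65, 0.64 and 0.568), A6C with T10G in library 1 at -1.86 kT (SD 0.579), and T12G with C14T at -1.81 kT (SD 0.565), with adjusted p of 3.12e-05 to 0.00012 over 16 or 20 contexts. The 4 pairs above 0, all in library 1, were A6C with G7A, G7T and G7C and G9T with T10C, at 0.76, 0.71, 0.57 and 0.58 kT. None of the 90 pairs of library 2 or the 83 of library 5 passed, while 89 and 56 of them had an adjusted p under 0.05. Without sites within 1 kT of the weakest 5% of a library, 3 of 150 pairs passed, and the pairs of positions 12 and 14 could not be formed. Of the 24, G9T with T10C was among these 3, and the others, named after their values were seen, were G8C with G9A in library 1 at 0.53 kT and G7T with T10G in library 5 at -0.59 kT ± 0.295 (SD, n = 65 contexts, adjusted permutation p = 4.84e-05), which was -0.23 kT over all contexts. A6C with G7T, A6C with G7A and A6C with G7C had 3, 2 and 3 contexts left, too few to pass, with means of 0.68, 0.43 and 0.11 kT. With the ratio of the weakest sites subtracted, 52 pairs passed, in a setting where the error from reverse-complement pairs rose to 0.487 kT.

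In library 1, mirrored changes in the left and right half-sites had close mean energies, and none of 3 mirrored pairs passed the test of their difference: A6C minus T10G was 0.14 kT ± 0.509 (SD, n = 30 contexts, adjusted permutation p = 0.333), A6G minus T10C 0.021 kT ± 0.239 (SD, n = 32) and A6T minus T10A 0.028 kT ± 0.352 (SD, n = 32). The pattern of library 1 is its own reverse complement, so over all spacers both sides hold the same duplexes read in opposite directions. Apart from read direction and unlisted sites, these differences were small by design and cannot test the symmetry of the half-sites. In library 2, 3 of 6 passed, with differences of 0.12 kT ± 0.124 for A6C minus T10G, -0.066 kT ± 0.122 for A6G minus T10C and 0.048 kT ± 0.158 for C5A minus G11T (SD, n = 64 contexts, adjusted permutation p = 9e-05, 0.00018 and 0.0494). All mirrored means of library 2 lay between 4.05 and 4.20 kT, at the level of the negative control, so they hold little information on symmetry. As single changes from the reference, the left change was the weaker binder in all 6 mirrored pairs, by 0.034 kT ± 0.065 (counting SE) for C5G and G11C to 0.61 kT ± 0.038 (counting SE) for A6T and T10A, and no test was run on these.

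The same duplex read in opposite directions gave close energies. Over 238 reverse-complement pairs of library 1, Pearson's r was 0.977 and Spearman's rho 0.97 (permutation p = 1e-05 for both), and r was 0.976 without the 2 pairs farthest from the median. The SD of the differences was 0.199 kT per site against 0.166 kT from counting error alone. Sites are not independent replicates.

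The experiments ranked the sites they shared alike but on different scales. Over 32 shared sites, r was 0.883 and rho 0.92 (permutation p = 1e-05 for both), and r was 0.909 without the 2 sites farthest from the median. The slope of library 5 on libraries 1 to 4 was 0.536 ± 0.0565 (bootstrap SD), and the RMS difference of 0.868 kT was above the RMS counting SE of 0.159 kT. Energies spanned 4.37 kT in the first experiment and 3.31 kT in the second. The 3 sites that differed most were AGAACAGGGGGTTCT, at 3.13 kT with libraries 1 to 4 and 1.29 kT with library 5, AGAACATGATGTTCT, at -0.29 and 1.43 kT, and AGAACAGGCGGTTCT, at 4.01 and 2.41 kT. Library and experiment changed together, so a difference between them cannot be assigned to either.

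**Figure D4:**
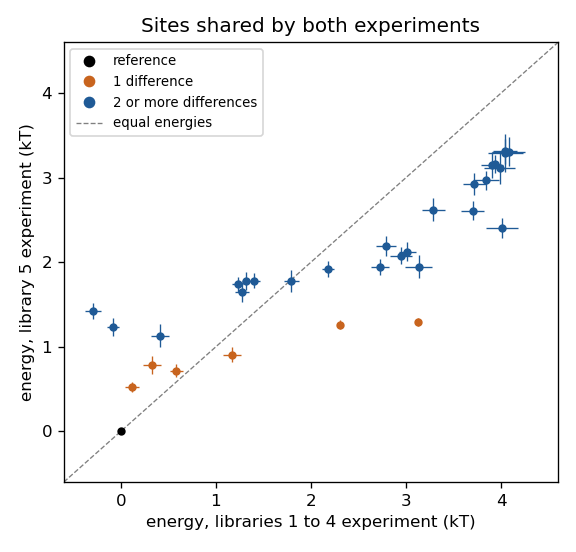
Energy (kT) of the 32 sites measured in both experiments, libraries 1 to 4 on the horizontal axis and library 5 on the vertical axis, with counting SE, where black is the reference, orange the one-base variants and blue the sites with 2 or more differences from it. The blue points follow a slope of 0.451, the orange points lie below them, and the dashed line marks equal energies.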

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

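The thinning test was chosen before its result was seen, and the other tests of explanations in this part were chosen after the results that prompted them. The tests on the reference of library 1 and on the share of misreads needed were added after those on the reference of library 5 and on the intercept had been seen, and all 4 are given.

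The effects of 2 substitutions differed between the experiments over matched contexts measured in both. T10G weakened binding by 2.56 kT ± 0.568 (SD, n = 16 contexts) with libraries 1 to 4 and by 1.34 kT ± 0.369 (SD) with library 5, a difference of -1.22 kT ± 0.718 (SD) in the same direction in 15 of 16 contexts (two-sided permutation test, adjusted p = 0.00048 over 6 substitutions). G7T gave -0.48 kT ± 0.357 (SD) with libraries 1 to 4 and 0.012 kT ± 0.436 (SD) with library 5, a difference of 0.49 kT ± 0.548 (SD) in the same direction in 11 of 16 contexts (permutation test, adjusted p = 0.0084). These contexts include the reference. Over all contexts of library 5, G7T gave -0.28 kT and was tighter in 1018 of 1152, the same direction as in library 1. The other 4 substitutions tested, A6T, G9A, G9C and G9T, had adjusted p of 0.497, 0.105, 0.867 and 0.0938, by exact or permutation test.

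The narrower energy range of library 5, with a slope of 0.536 over 32 shared sites, was set against 3 technical explanations. Misreads of the abundant reference would spare sites with 2 or more differences from it, but their slope was 0.451 ± 0.0465 (bootstrap SD, n = 25). Read depth would flatten the first experiment when it is thinned to the depth of the second, but the thinned energies had a slope of 0.979 ± 0.0084 (bootstrap SD) on the full ones. A shifted zero moves all sites but the reference by one constant, but the differences between experiments had an SD of 0.821 kT ± 0.101 (bootstrap SD, n = 31), against an RMS counting SE of 0.161 kT. No biological explanation was tested, and library and experiment cannot be told apart.

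At the tight end, where shared sites lay weaker in library 5, a shifted zero stays open. The reference of library 5 lay -1.26 kT from the energy predicted by an additive model with a floor, fitted without it and its one-base variants (RMS residual 0.197 kT), but the same prediction missed the one reference of the other experiment by 0.0298, 0.89 and -0.30 kT in libraries 1, 2 and 3 (RMS residuals 0.30, 0.11 and 0.178 kT), so neither a shift nor its relation to the share of reads taken by the reference can be read from it. The intercept was 0.73 kT over all shared sites and 1.11 kT without the reference and its one-base variants. The reference lies at 0 by definition and those variants lay below the other shared sites, so leaving them out raised it in any case. This comparison cannot decide on misreads as the whole cause. The 14 one-base variants of library 5 were tighter than predicted by 0.51 kT on average. As misreads, they would need a median of 0.268% of the reference's reads. This is above 2 times the median of 0.0808% of the one-base variants outside the design. It lies within their range of 0.0171% to 0.722%, but only through G8A at the top. The next highest, T12C, had 0.191%. Misreads stay open for the 14 variants on G8A alone. The one-base variants of libraries 1, 2 and 3 lay weaker than predicted, by 0.38, 0.41 and 0.18 kT on average.

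Library 5 was sequenced with 444 sites outside its design, and 244 of them share the form NGAACNTGANGTTCN, with positions 1, 6, 10 and 15 varied around the spacer TGA. All 256 sites of the form were listed, 12 of them within the design. Misreads of library 5 sites would give other spacers a like number, but the next spacer of the design, GGG, had 1.64% as many. The effects of mirrored substitutions ranked alike, with a Spearman's rho of 1 over 6 pairs (exact one-sided permutation p = 0.00139), which is consistent with binding that follows the sequence. The sources used here do not describe this set, and whether it was added on purpose was not tested.

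Among the sites outside the design were 13 one-base variants of the reference, with energies of -0.31 to 1.58 kT and a median of 0.0808% of its bound reads, and 4 of the 13 were called weaker than it. In the 10 of these also measured with libraries 1 to 3, the median energy was 1.15 kT there and 0.23 kT with library 5, and 9 were tighter with library 5. Misreads of the reference would take like shares of its bound and unbound reads, and the 13 variants had medians of 0.0808% and 0.0992%. Whether their reads are misreads is left open, so their library 5 energies may not be those of the named sites. A further 132 sites outside the design had A at position 8, with 0.109% of the bound and 0.195% of the unbound reads, and 13 of them had at least 50 reads, at a median of 1.89 kT.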

How the results depend on the processing

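The settings with the reference predicted by a floor model, with a common floor, with misreads at the measured share and without the reference and its one-base variants were chosen after the data were seen, and all others before. Of the summary values, 95 counted as kept and 29 did not. Tested values had to keep their direction and side of the threshold, and others had to stay within their spread, a bootstrap SD over sites. Counts of calls were compared by size alone, whichever calls made them up. The count of one-base variants called was thus kept with the floor-model reference, although library 5 went from 14 weaker to 1 weaker and 5 tighter. Of the single effects, 1138 kept their direction and side of the threshold, 15 newly passed, 34 no longer passed and 38 changed sign. There were no replicates, the lowest depth was 51 and 22 reads per site, and some weak sites rest on few bound reads. Unless stated, the cause was not tested.

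The error from reverse-complement pairs was 0.151 kT with at least 200 reads, 0.17 kT with 5 added to each count, 0.223 kT with misreads subtracted at 0.1% and 0.487 kT with the ratio of the weakest sites subtracted. That subtraction gave a slope between experiments of 0.454, 52 pair dependences, 1 mirrored difference and -0.046 kT for C5A against G11T, which changed sign. It gave an additive model R2 on left-out sites of 0.852 in library 1, 0.649 in library 3 and 0.904 in library 5. For library 1, R2 was 0.922 with at least 200 reads, 0.872 with 5 added and 0.922 with only sites within 2 substitutions. For library 2 it was 0.161 with misreads at 0.1%, -0.15 weighted by inverse counting variance and 0.51 within 2 substitutions. For library 3 it was 0.472 weighted, 0.726 within 2 substitutions and 0.478 without the reference and its one-base variants. For library 5 it was 0.924 weighted and 0.931 within 2 substitutions. With a common floor it was 0.942, 0.805, 0.92 and 0.937 in libraries 1, 2, 3 and 5. The slope without the reference and its one-base variants was 0.451. Pair dependences numbered 3 in contexts with the reference half-sites and 3 without sites within 1 kT of the weakest 5%, where fewer pairs could be tested.

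With the reference predicted by the additive model, 21 one-base variants were called, 10 weaker and 5 tighter in libraries 1 to 3 and 6 tighter in library 5. The energies that changed sign in libraries 1 to 3 were -0.092 for G11A, -0.23 for G11T, -0.64 for T12A, -0.40 for T12C, -0.24 for T12G, -1.63 for T13A, -1.40 for T13C, -0.73 for T13G, -0.36 for T15A, -1.58 for T15C and -0.39 kT for T15G. In library 5 they were -0.55 for A1G, -0.22 for A3C, -0.30 for A3G, -0.29 for A3T, -0.0899 for A6T, -0.83 for G7T, -0.84 for G8T, -0.57 for G9A, -0.45 for G9C, -0.63 for G9T, -0.059 for T10G, -0.18 for G11A, -0.55 for T13A and -0.17 kT for C14T. This model leaves out the floor and fits libraries 2 and 3 poorly. With the reference predicted by the floor model, those that changed sign were all in library 5, at -0.46 for A1G, -0.13 for A3C, -0.21 for A3G, -0.19 for A3T, -0.74 for G7T, -0.75 for G8T, -0.48 for G9A, -0.36 for G9C, -0.54 for G9T, -0.089 for G11A, -0.46 for T13A and -0.077 kT for C14T. G11A, T13A and C14T there lie outside the library 5 design. Fisher p-values stayed against the reference as read. With misreads subtracted at 0.1%, 25 of 31 variants of libraries 1 to 3 could be measured.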

Other observations

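The floor and read minimum tests in this part were chosen before their results were seen, and the comparisons of the TGA sites and the test on counting error were chosen after.

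The sites with the spacer TGA add bases that library 5 left out at positions 1, 6 and 10, and position 15, which it held fixed. In this form A6C weakened binding by 1.25 kT ± 0.397 (SD, n = 56 contexts) and its mirror T10G by 1.25 kT ± 0.333 (SD, n = 62). A6T and T10A gave 0.79 and 0.78 kT, A6G and T10C 0.59 and 0.59 kT, A1C and T15G 0.61 and 0.63 kT, and A1T and T15A 0.49 and 0.58 kT. A1G was tighter, at -0.26 kT ± 0.285 (SD, n = 60), in all but 11 contexts, while T15C gave -0.0092 kT ± 0.239 (SD, n = 63, two-sided permutation, adjusted p = 0.76). The other 11 effects each had an adjusted p of 1.09e-05 in the permutation test. The tightest site outside the design in this set was GGAACATGATGTTCC, with palindromic half-sites, at 0.66 kT ± 0.205 (SE), and the weakest was CGAACCTGAGGTTCA at 4.69 kT ± 0.489 (SE), both named after their values were seen. Over 12 sites outside the design that both experiments measured, r was 0.909 (permutation p = 5e-05), rho 0.874 (permutation p = 0.00043) and the slope 0.395, and r was 0.863 without the 2 farthest.

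The 20 substitution pairs that bound tighter than the sum of their energies may reflect a weakest energy that the assay can record. With a fitted floor, 100% of them had a dependence under 0.5 kT in size, and their median went from -1.13 to -0.0027 kT. The counting SE of their means was 0.035 to 0.094 kT, while a call needed over 0.5 kT, which argues against counting error alone. Given that rule and those SEs, 100% of the 20 had to lie below 0 by more than 2 counting SE. They did so by 7.88 to 58.6 times the SE. With at least 200 reads per site 95% were still called, a minimum that only 1 of 256 sites of library 3, which holds 17 of the 20, fell below. In library 1, where 115 of 490 sites fell below it, 2 of 3 were still called. Whether the floor is nonspecific binding or free DNA carried into the bound band was not tested. Of the 4 pairs above 0, A6C with G7A and G9T with T10C were still over 0.5 kT with the floor, at 0.67 and 0.64 kT.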
